A study of Oryza sativa with 52 samples.

How the data were processed

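Total RNA of 52 leaf samples was reverse-transcribed, labelled with Cy3 or Cy5 and hybridised to 26 custom Agilent arrays on 7 slides, 2 samples of opposite dye per array, per the labels. Each channel holds a sample of its own and there is no common reference. Each array gives a mean spot intensity, a local background intensity and a processed intensity per channel, made with Agilent Feature Extraction 10.5.1.1, per the file headers. The flags for spots well above background, saturated or outlying are the scanner software's own yes or no values, per the file headers. The submitters' processing notes also name affy, with no version or role. The deposited values hold log2 values of 125722 probes, whose order within each sample was identical to that of the processed intensity of its own channel (Spearman correlation of 1) and whose medians were nearly equal across samples. It leaves out 26156 rice spots, and how its values were centred is not given in the sources used here.

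The groups came from the labels for days between transplanting and sampling, and all columns of samples in the files could be tied to a sample. Mean intensities were corrected with normexp against the local background with an offset of 50, normalized within arrays by loess with control spots at weight 0 and between arrays by Aquantile, and split into 1 log2 value per channel (limma 3.58.1 in R 4.3.3, with files read by version 1.17.8 of data.table). Normalization of this kind removes any shift shared by all probes, so every difference is relative to the typical probe. Control spots were then left out, with 401 probes whose spots carried outlier flags, and spots of identical sequence were averaged. A probe was tested if it was well above background in at least 7 of the 13 samples of a series, which kept 96065 of 148440 probes. No spot was saturated, and the correlation of spike-in signals with their known amounts was between 0.983 and 0.993 on every array.

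The design had been fixed before the data were examined, with 1 probe per gene, lists of genes and named genes. The probes could not be paired with genes, since the files give no gene names and the list of rice genes given shares no identifiers with them. Every probe was therefore tested on its own, the gene lists and the mean over probes of a gene were not run, and at most 2 probes in each direction were named per comparison. Named probes were those with the largest effect among called probes, for date and transplanting among those with the same sign in at least 24 of 26 matched pairs, and for the daily rhythm among those called in every series.

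Models were fitted with lmFit and eBayes with a trend, with the array as a random block whose correlation was estimated on 4000 probes, and p-values were adjusted by the Benjamini-Hochberg method. The daily rhythm was fitted with cosines and sines of 24 and 12 h beside series and dye, and within single series with the 24 h period alone. A probe was called rhythmic with an adjusted p under 0.05 and a fitted range of at least 1 on the log2 scale. Date, transplanting and their interaction were fitted together with sampling time as 13 levels and dye. Differences of daily curves were tested as products of date or transplanting with the 4 rhythm terms, and the 24 h return on the 8 samples at 08:00 with series and dye. That fit and those within single series took the array correlation of the rhythm fit over all series. Where a probe was not well above background in any sample of a group, a lower bound of the fold was computed against the lowest signal among probes well above background in each sample. Bounds across channels are open to dye bias.

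Slides follow the series closely. Slide 1 holds the first 6 samples of the 64-day series, slide 3 samples of the 56-day series, slide 4 of the 84-day series and slide 6 of the 92-day series. Slides 2, 5 and 7 hold samples of a pair of series each. The 6 samples of slide 4 were scanned on another day than the rest. Slide was tried as a random block and as a fixed term, and scan day as a fixed term.

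The tests were checked on simulated data with the array correlation set to 0.4 and 200 of 96065 probes changed. At log2 changes of 0.5, 1 and 2, the date test recovered 91.0%, 100% and 100% and the transplanting test 91.0%, 98.5% and 100%. The interaction test recovered 52.2%, 89.6% and 98.5%. The 24 h return test recovered 0%, 1.49% and 74.2%, which does not describe the real data, where 13437 probes with a median absolute difference of 0.43 were called. At simulated ranges from trough to peak of 0.5, 1 and 2, and with no requirement on range, the rhythm test over all series recovered 64.2%, 98.5% and 100%, and that within the 64-day series 1.49%, 38.8% and 90.9%. False calls numbered between 1 and 13 per test. The simulated data held no differences between slides, so neither recovery nor false calls cover slide effects in the real data.

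Alternatives fixed before the data were examined were other background corrections and scalings, the deposited value table, other filters on dim probes, no dye term, no array block, slide terms, a robust variance prior, other shapes of the daily curve, other size thresholds and each time or series left out. Runs with another choice of probes, with a time or series left out, or on 1 date or transplanting alone kept the array correlation of the fit to all samples. Runs without slide 1 or without slide 4, with scan day, on 1 date alone for transplanting, with a daily curve per date in the test of curves between transplantings, and with 1 probe per group of overlapping probes were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.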

Results

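Leaves of the rice variety Koshihikari, a japonica table rice, were collected in a paddy field in Sapporo, Japan, and their total RNA was measured on 2-colour oligonucleotide arrays. The 52 samples form 4 series of 13, each series covering 24 h from 08:00 to 08:00 in steps of 2 h. Plants transplanted on May 22 were sampled 64 days later in July and 92 days later in August. Plants transplanted on May 30, 8 days after the others, were sampled on the same days, 56 and 84 days after transplanting. Each time point of a series is 1 sample with no replicate, and each date is 1 day. The error of every test except that of the 24 h return is therefore the spread around a fitted pattern over the times of its series. It is not the spread between days, fields, plots or plants. The return test uses samples at 08:00 alone, and its error rests on how far the transplantings of a date differ in their return. Other differences between the plants of each transplanting cannot be told apart from transplanting.

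Between 59.3% and 72.8% of the rice probes were well above background per sample, and 96065 probes entered the tests. The highest of these shares, 64.5% and above, were those of the 6 samples on slide 1, the first 6 times of the 64-day series, against at most 63.9% in the 46 others. The number of arrays limits the precision of every value. The files pair the probes with no gene name and place 0 of the 151878 rice spots in the genome, so probes are given by their ID, and all counts are of probes, not genes. Several probes can report on 1 transcript: the 148440 probes kept after flags fell into 102445 groups that share 25 or more bases of sequence.

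**Figure D1:**
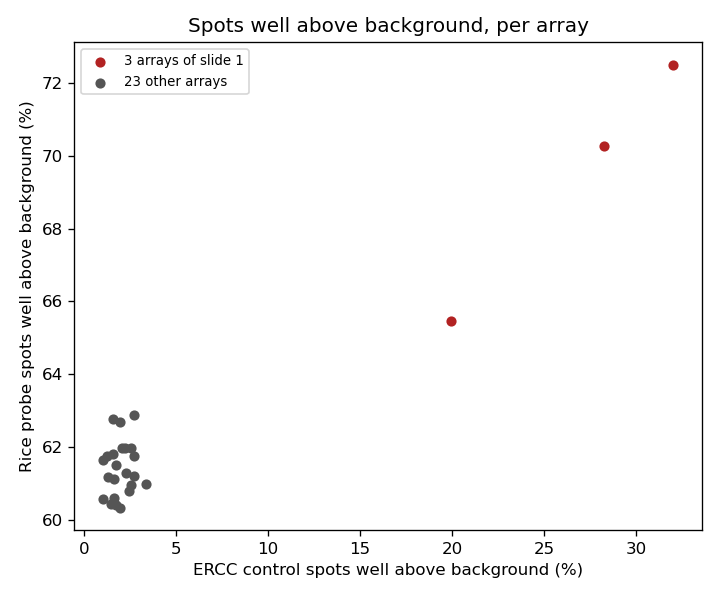
Rice probe spots well above background (vertical axis, %) against ERCC control spots well above background (horizontal axis, %), 1 point per array with both channels combined. The 3 arrays of slide 1 lie at 19.9%, 28.3% and 32.0% of ERCC spots, and the 23 other arrays between 1.04% and 3.40%.

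Time of day and date were the main axes of variation. The first and second principal components held 43.4% and 23.5% of the variance and arranged the times of each series along a loop. The third, with 10.4%, separated the dates without overlap, with July samples between 12.5 and 84.0 and August samples between -85.0 and -31.9. Samples of 1 series taken 12 h apart differed by a median absolute log2 value of 0.44 per probe, and neighbours 2 h apart by 0.17. Pairs matched for hour and transplanting differed by 0.27 between dates, and pairs matched for hour and date by 0.17 between transplantings. The standard deviation between duplicate spots of 1 probe on an array was 0.16.

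**Figure D2:**
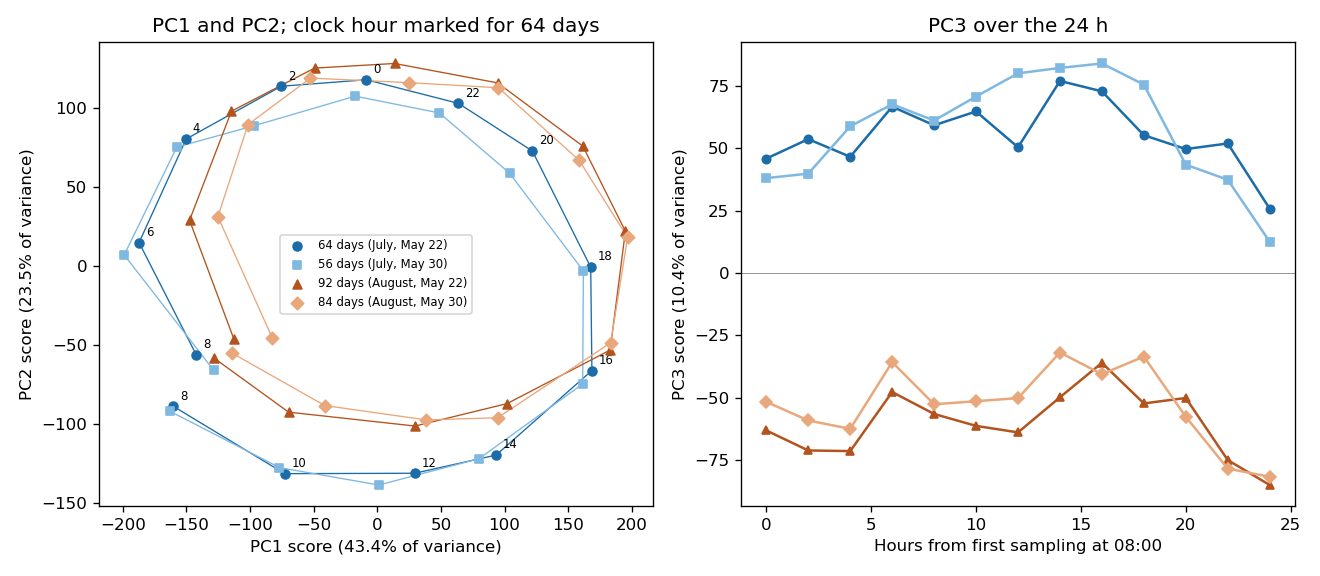
Scores of the 52 samples on the first 3 principal components, with PC1 against PC2 in the left panel and PC3 against hours from the first 08:00 sampling in the right panel; points are samples, lines join the times of a series, and clock hours are printed for the 64-day series. PC1 and PC2 follow the hour of day in all 4 series, and PC3 runs from 12.5 to 84.0 in July and from -85.0 to -31.9 in August.

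The first question was which transcripts follow the time of day. Over all 4 series, 34281 of the 96065 probes, or 35.7%, followed a daily curve with a fitted range from trough to peak of at least 1 on the log2 scale. Probes 44kb3_11643 and 44kb3_960 had the largest ranges among those called in every series, 10.76 and 10.62, and both peaked at 5.4 h in clock time. Their values ran close together sample by sample, so they may report on the same transcript. Probe 44kb3_11643, with the sequence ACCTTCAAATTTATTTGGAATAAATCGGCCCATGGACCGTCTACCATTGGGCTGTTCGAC, moved by 10.35 in July and 11.17 in August, and its limma adjusted p was 2.57e-30. Fitted peaks fell at every hour of the day, with 4931 probes (14.4%) in the bin from 14 to 16 h and 3819 in that from 4 to 6 h. The tallest bin depended on the shape fitted: with the 24 h period alone it was that from 16 to 18 h with 4156 probes, followed by 4 to 6 h with 3856, while 14 to 16 h held 2820.

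The test was limma's moderated F over cosines and sines with periods of 24 and 12 h, with Benjamini-Hochberg adjustment. Within single series, 35499 probes were called at 64 days, 33553 at 56 days, 32006 at 92 days and 29780 at 84 days, and 22632 were called in every series and over all 4. Without the requirement on range, 85497 probes passed the adjusted threshold, and with 1 probe kept per group of overlapping probes, a choice made after the data were seen, 21794 were called.

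**Figure D3:**
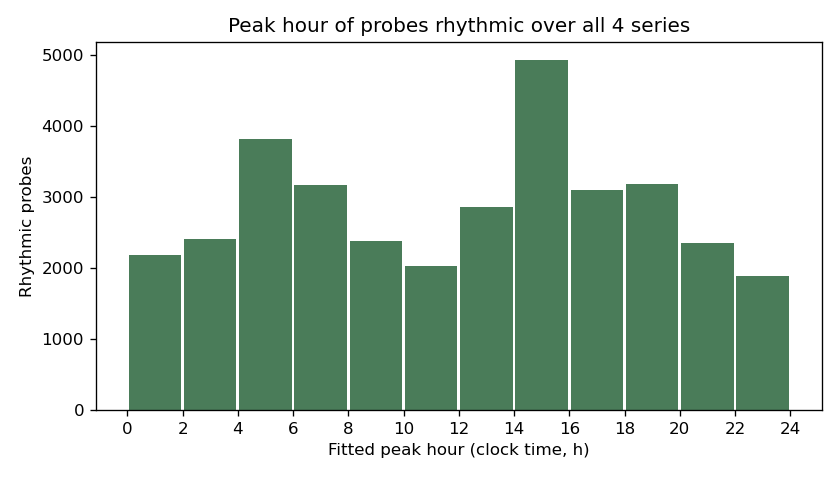
Number of probes (vertical axis) by fitted peak hour in clock time (horizontal axis, h), in bins of 2 h, for the 34281 probes called rhythmic over all 4 series. The tallest bar is at 14 to 16 h with 4931 probes, and the next at 4 to 6 h with 3819.

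The second question was whether the daily curves differ between the dates. The curve differed between July and August for 45048 probes, of which 28961 had the larger range in July and 16087 in August. The median range of these probes was 1.0 in July and 0.83 in August. Probes 44kb3_40833 and eAry1_19791, which overlap in sequence, were almost flat in July, with ranges of 0.21 and 0.20, and moved by 3.23 and 3.22 in August (limma adjusted p = 2.22e-11 and 1.10e-11). In the other direction, probe eAry1_49458 had a range of 6.61 in July and 1.87 in August (limma adjusted p = 3.44e-07), and probe eAry1_47512 one of 5.41 and 0.81 (limma adjusted p = 0.0349). The last of these was well above background in 23 of 26 July samples and 9 of 26 August samples, and lost its call under 12 of 28 other settings.

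Peak hours moved little between dates. Among the 22632 probes called in every series, the peak came later in August by a median of 0.3 h in plants transplanted on May 22 and 0.2 h in those transplanted on May 30, and 66.9% and 64.9% of the peaks stayed within 1 h. The largest median delay, 0.6 h and 0.5 h, was that of probes peaking between 14 and 16 h. With slide as a fixed term 25728 probes were called for a difference of curves, and with 1 probe per overlap group 28131.

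**Figure D4:**
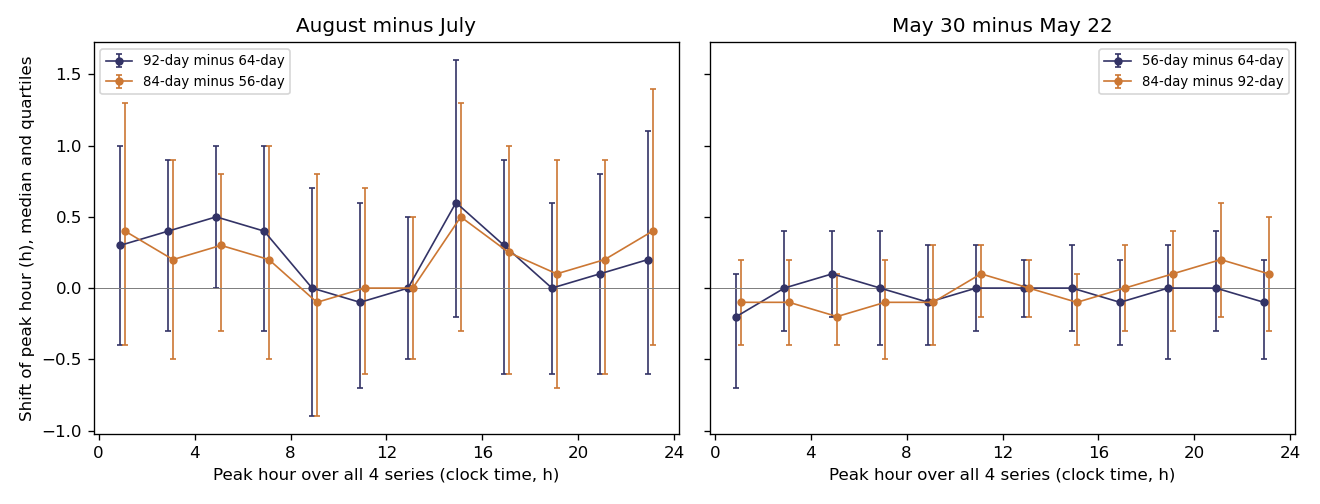
Shift of the fitted peak hour (vertical axis, h) against the peak hour over all 4 series (horizontal axis, clock time in h), for August minus July in the left panel and May 30 minus May 22 in the right panel. Points are medians and bars quartiles over the 22632 probes called in every series, with 1 line per matched pair of series; the medians at 14 to 16 h are 0.6 h and 0.5 h between dates and lie near 0 between transplantings.

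Few or no differences of the daily curve between transplantings were called. Of 96065 probes, limma called 0 after adjustment, with 2639 at an unadjusted p under 0.05. That fit gives both dates 1 curve. With a daily curve per date in the model, a choice made after the data were seen, 19 probes were called, 5 with the larger range in plants transplanted on May 30 and 14 in the others, with 7075 at an unadjusted p under 0.05. Adding slide as a fixed term, limma called 0 (6050 at an unadjusted p under 0.05). Peak hours of plants transplanted on May 30 differed from those transplanted on May 22 by a median of 0 h in July and -0.1 h in August, and 91.9% and 93.7% of peaks lay within 1 h. In simulated data the test with 1 curve recovered 62.7% of changes of 0.5 in log2 amplitude, from mean to peak, and 94.0% of changes of 1, but these data held no difference of curves between dates, so the real recovery is not known.

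The third question was which levels differ between the dates, which the study treats as developmental stages. Between July and August, 58485 probes changed, 30059 upwards and 28426 downwards, with a median absolute log2 difference of 0.28. The balance depends on the scaling: with the 75th percentile in place of Aquantile, 23621 were called higher and 37552 lower. A log2 difference of 1 or more was reached by 1046 of the higher and 1316 of the lower probes. At least 24 of the 26 pairs matched for hour and transplanting had the same sign for 9142 higher and 6794 lower probes. Probe 44kb3_10988 (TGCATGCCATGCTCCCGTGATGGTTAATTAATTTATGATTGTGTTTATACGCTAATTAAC) had means of 6.43 and 6.27 at 64 and 56 days in July and 13.70 and 12.22 at 92 and 84 days in August. It was higher in 26 of 26 pairs, and only 7 of 26 July samples were well above background, 6 of them on slide 1, where control spots and dim probes also had more signal, so the size of its rise rests on the background offset: the log2 rise was 6.61, and 9.63 with scanner processed signals. Probe 44kb3_29036, whose log2 rise was 6.57 and 10.20 in the same settings, was not well above background in any July sample and was well above it in 26 of 26 August samples, a rise of at least 80.9-fold, taken against the dimmest signals that count as above background. Its August values ran in parallel with those of 44kb3_10988, so both may report on the same transcript.

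Probe eAry2_47387 (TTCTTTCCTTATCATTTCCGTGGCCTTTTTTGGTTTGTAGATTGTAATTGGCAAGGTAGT) fell by 3.60 ± 0.21 (SE) on the log2 scale and was lower in August in every one of 26 pairs (limma adjusted p = 3.78e-17). Probe eAry1_47512 fell by 3.36 ± 0.55 (limma adjusted p = 2.25e-06), again lower in every pair, with 9 of 26 August samples well above background, so its size also rests on the offset. With scanner processed signals these differences were -4.64 and -5.40, in the other order. With slide as a fixed term both calls were lost, with differences of -1.78 ± 1.07 and -0.21 ± 2.86, while the rising probes 44kb3_10988 and 44kb3_29036 stayed called at 6.61 ± 0.42 and 6.77 ± 0.43. Differences of 1 or more were most frequent at 12:00, when the mean of both transplantings was higher in August for 3164 probes and lower for 2673.

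Slide and date are largely confounded, since only slide 5 holds samples of both. With slide as a random block 44799 probes were called, with slide as a fixed term 1899. Over the 58485 probes the median difference in the original direction was 0.28 with a median SE of 0.06, and with slide as a fixed term 0.25 with a median SE of 0.29. Slide 5 holds a single pair at 08:00, the first sample of the 92-day series and the last of the 56-day series. They differ in transplanting as well as date, and the 24 h return is mixed in. The same sign was seen there for 71.9% of called probes (88.2% of those with a difference of 1 or more). Both samples were part of the fit that gave the calls, which by itself raises these shares, so they are no independent check. In that pair the rising probes differed by 7.78 and 7.60 and the falling probes by -2.36 and -7.24. In plants transplanted on May 22 alone, 38862 probes were called, and with 1 probe per overlap group 37752.

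**Figure D5:**
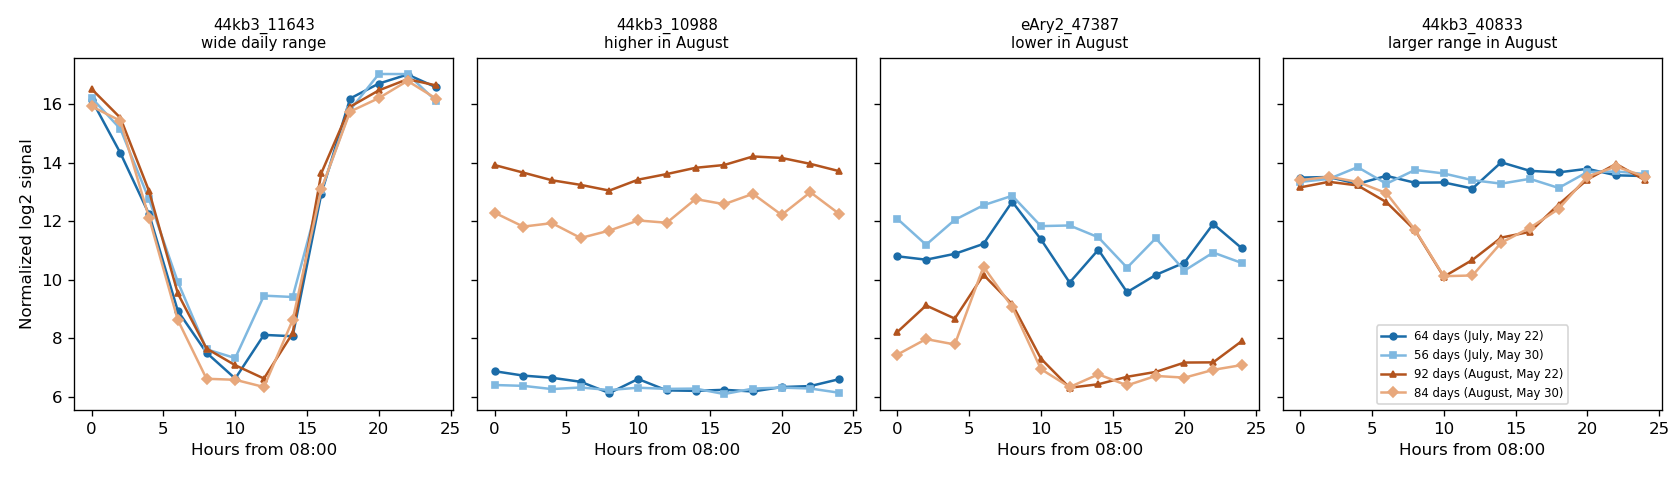
Normalized log2 signal (vertical axis) of 4 probes against hours from the first 08:00 sampling (horizontal axis), 1 line per series and 1 sample per point. From left to right: a probe with a wide daily range, one that rose and one that fell from July to August, and a probe whose daily range was 0.21 in July and 3.23 in August.

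The fourth question was whether plants transplanted 8 days apart differ when sampled on the same day. The difference was smaller than that between dates: 12754 probes were called, 5823 higher and 6931 lower in plants transplanted on May 30, with a median absolute log2 difference of 0.21. With the 75th percentile in place of Aquantile, 4127 were higher and 8194 lower. Only 43 higher and 137 lower probes reached a difference of 1. Probes eAry2_44882 and 44kb3_37444 were higher by 1.34 ± 0.17 and 1.32 ± 0.19 (SE), in 25 and 26 of 26 pairs (limma adjusted p = 2.46e-06 and 1.55e-05). Both differed more in August: in fits to 1 date the differences were 0.61 and 0.81 in July and 2.06 and 1.84 in August. Of the 92-day samples, 6 of 13 were well above background for eAry2_44882, whose difference was 2.09 with scanner processed signals. Probes 44kb3_18542 and eAryKoshi_02745, which overlap in sequence, differed by -1.95 ± 0.42 and -1.94 ± 0.42 and were higher in only 2 of 26 pairs (limma adjusted p = 0.00269 and 0.00270).

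The transplanting count changed with the treatment of slides: it was 3549 without the 6 samples of slide 1, a choice made after the data were seen, 4215 with slide as a random block and 0 with slide as a fixed term (limma, 10428 at an unadjusted p under 0.05). Over the 12754 probes the median difference in the original direction was 0.21 with a median SE of 0.06, against 0.15 and 0.06 without slide 1, 0.19 and 0.07 with the random block and 0.19 and 0.15 with the fixed term. Probe 44kb3_18542 lost its call at -1.71 ± 0.51 without slide 1 and at -1.80 ± 1.28 with the fixed term. The count was 21508 with no array block, 19505 with scan day as a term and 27451 with the 26 matched pairs as a block, and in the 08:00 pairs on slides 2 and 7, 61.9% and 85.1% of called probes had the same sign. These pairs set the first 08:00 of plants transplanted on May 30 against the last 08:00 of the others, with opposite dyes, so the 24 h return and dye are mixed into them. Their samples were also part of the fit that gave the calls, which by itself raises these shares.

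The transplanting difference itself depended on the date for 16506 probes, with 9062 shifted upwards and 7444 downwards in August relative to July. The balance was 10664 and 5802 with the 75th percentile in place of Aquantile, and turned to 1562 upwards and 2849 downwards with slide as a fixed term. From the fit to all 52 samples, 9911 probes were called within July and 17052 within August. Of the 1523 called on both dates, 599 had the same sign, where independent lists of these sizes would share 862, and 924 the opposite sign, where they would share 897. Separate fits to the 26 samples of each date, which give each date its own sampling times and were chosen after the data were seen, called 22424 and 32972. Of their 7533 shared probes, 2833 had the same sign (3841 for independent lists) and 4700 the opposite sign (3856). Slides 3, 5 and 6 against the rest place 50 of the 52 samples as this contrast does. A difference between those slides could therefore also give opposite signs on the dates. Probes 44kb3_35348 and eAry1_33616, overlapping probes, had the largest upward difference, 4.30 ± 0.98 and 4.13 ± 0.98 (SE; limma adjusted p = 0.00250 and 0.00339). For 44kb3_35348, means were 16.42 and 15.67 at 64 and 56 days in July but 10.39 and 14.69 at 92 and 84 days in August. With slide as a fixed term these differences were 1.19 ± 2.26 and 1.11 ± 2.25 and no longer called, and with slide as a random block 4.44 ± 1.39 and 4.27 ± 1.39, also not called. Probes 44kb3_37338 and eAry1_24410 had the largest downward differences, -5.42 ± 1.46 and -5.01 ± 1.39 (limma adjusted p = 0.00905 and 0.0110). Their sequences overlap by just under the 25 bases that define a group, so they are not separate findings. At 84 days 6 and 7 of 13 samples were well above background, and the differences reached -7.87 and -7.43 in other settings. Both lost their call with slide as a fixed term at -3.79 ± 3.30 and -3.57 ± 3.15 and with the random block at -5.68 ± 2.09 and -5.35 ± 2.03. With slide as a random block 2840 probes were called for this difference, with slide as a fixed term 4411 and with no array block 29371.

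The last question was how far leaves return to the same state after 24 h. Between the first and last 08:00, which lie 1 day apart, pairs of samples differed by a median absolute log2 value of 0.20, against 0.17 between neighbouring times. Each of these 08:00 pairs crosses slides and dyes, while many neighbouring pairs share an array and most a slide. The values are therefore not like measures. The fit to the 8 samples below also compares across slides, and its series, dye and return terms leave little for the error. In the 8 samples at 08:00, 13437 probes were called, 9369 higher and 4068 lower after 24 h, with a median absolute log2 difference of 0.43. A difference of 1 or more was reached by 808 of the higher and 98 of the lower probes. The change differed between dates for part of the probes. A fit to all 52 samples, which estimates dye from every hour, called 12998 probes for a difference of the return between August and July. That fit also called 13153 probes for the mean return of both dates, 8631 higher and 4522 lower. With slide as a fixed term 1022 of the 12998 were still called, so slide stays open for this difference. Over probes, the differences after 24 h correlated at 0.675 and 0.609 between series of 1 date and at -0.307 and 0.0326 between dates, where dye runs the same way within a date and adds to this contrast. Probes 44kb3_37338 and eAry1_24410, whose sequences partly overlap, had mean differences of 4.40 ± 0.63 and 3.97 ± 0.64 (SE; limma adjusted p = 0.0108 and 0.0149). These describe neither date: for 44kb3_37338 the difference was 10.96 and 5.73 at 64 and 56 days in July but -0.32 and 1.23 at 92 and 84 days in August. The dye term takes up that contrast of dates, so the SE leaves it out. Left-out series moved 44kb3_37338 to between 3.09, without the 64-day series, and 5.71, without the 56-day series, and it lost its call without the 84-day series at 4.01. Probe eAry1_24410 moved to between 2.60 and 5.33 and lost its call without the 84-day series at 3.75 and without the 92-day series at 4.18. Probes eAry1_23967 and 44kb3_37104 changed by -2.18 ± 0.51 and -2.17 ± 0.46, being higher in only 1 of 4 series (limma adjusted p = 0.0405 and 0.0321), and lost their call in 9 and 8 of 14 other settings. Their values ran close together sample by sample, so they may report on the same transcript. They stayed called only without the 92-day series, at -3.22 and -3.12, among the runs with a series left out. Without the 84-day series they were -1.13 and -1.21, without the 64-day series -2.45 and -2.42, and without the 56-day series -1.90 and -1.91.

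This count depends on the dye term, since in these 8 samples the dyes run opposite ways in July and August: with no dye term limma called 0 probes, with 11609 at an unadjusted p under 0.05. Higher probes were 69.7% of the calls, but between 51.3% and 56.5% with other scalings and with the deposited value table. The count was 5599 with no array block and when a series was left out 1144 without the 84-day, 4050 without the 92-day, 8554 without the 64-day and 12359 without the 56-day series.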

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

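The comparison of raw signals between dim and bright probes with its pairs outside slide 1, the readings of ERCC spots and local background on slide 1, the runs without slide 1, the jackknife, the fit with a daily curve per date for transplanting and the splits by whole slides were chosen only after the result was seen.

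Signal appeared in control spots that the comparisons do not use. On slide 1, which holds the first 6 samples of the 64-day series, 26.74% of ERCC spots and 30.5% of ETG spots were well above background, against 1% of its negative-control spots. ERCC spots were well above background at 1.04% to 3.40% on the 23 other arrays, and the 6 samples of slide 1 also had more rice probes well above background, 64.5% to 72.8% against 59.3% to 63.9% in the 46 others. The tables argue against a higher local background, since its median in the samples of slide 1 lay within the range of the other slides in each dye. The 1% of negative-control spots on slide 1 also lies within the 0.583% to 1.60% of the other slides. That flag is set relative to background, so this share is a weak test by itself. The ERCC share does not lie within the range of the other arrays. The tables also argue against more labelled material. Against samples of the same dye and hour on other slides, the raw log2 ratio of dim probes exceeded that of bright probes by 0.62 ± 0.14 (SD, n = 6). A larger amount would have raised both. In 5 of these 6 comparisons the other sample is an 84-day sample of August. In the 17 July and August pairs of the same dye and hour outside slide 1, that excess was 0.07 ± 0.13 and at most 0.32, under the lowest of slide 1, 0.39. Against 56-day samples of the same date, mostly of the other dye, the excess was 0.60 ± 0.52. Labelled RNA that bound without a matching sequence stays open, since the 26.74% of ERCC spots is the observation itself and no independent test of it was run, and no biological explanation was tested.

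The daily curve differed between July and August for 45048 probes, a difference between groups in the same contrast. A chance division of single samples is argued against: 1 of 100 splits of the samples, the real one, called as many. The highest of the others called 5072 where their median was 0, which points to a structure of the samples. Random splits leave the real difference in the residual spread, which lowers their counts, and break up arrays and slides. Of 10 splits by whole slides, 24 samples against 28, 0 called as many, and the highest called 12045 but places 42 of the 52 samples as the dates do. The 6 samples of slide 1 are argued against as the whole cause, since without them 78.3% of the called probes were still called (jackknife SE over times 5.04 percentage points). Slide stays open, as 52.2% were still called with slide as a fixed term (SE 11.9 percentage points) and only 1 slide holds both dates. The date itself, with plant age, day length and weather that change with it, also stays open and untested, so slide and date cannot be told apart for the rest of these probes.

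The return to 08:00 after 24 h differed between August and July for 12998 probes in a fit to all 52 samples. Dye alone is argued against, because that fit estimates dye from every hour and still called these 12998 probes. Slide stays open. With it as a fixed term 1022 of these probes, 7.86%, were still called, while their median difference was 0.60 with a median SE of 0.25, against 0.70 and 0.19 without slide, so calls were lost with most of the difference kept. In another fit, whose daily curve and return are common to both dates, slide raised the calls from 8270 to 10757, and 68.7% of the former remained. That share passes the limit set beforehand but not beyond its spread, since it was 1.28% without the 56-day, 62.7% without the 64-day, 67.4% without the 92-day and 78.7% without the 84-day series (jackknife SE 52.2 percentage points). Weather on the days in question is untested, and the 35 splits of the 8 samples are too few in distinct fits for a share under 0.05, with 13437 probes in the real split, 5 splits that give this same fit and 0 probes as the highest of the others.

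The transplanting difference depended on the date for 16506 probes, which marks it as a difference between groups. A chance division of single samples is argued against: only 1 of 100 splits, the real one, called as many, and the highest other called 1. Random splits leave the real difference in the residual spread, which lowers their counts, and break up the slides. Slides are not covered by this: 4 of 10 splits by whole slides called as many, the highest 23015, with slides 2, 3 and 5 against the rest. Slides 3, 5 and 6 against the rest called 15588 and place 50 of the 52 samples as this contrast does. Slide and this contrast can therefore hardly be told apart. With slide as a random block 2840 probes were called, and with slide as a fixed term 4411, of which 2087 were among the 16506.

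A chance order or division of single samples is also argued against for the 34281 rhythmic probes, with 0 as the highest of the other orders of the times. The same holds for the 58485 probes between dates, with 0, and for the 12754 probes between transplantings, with 1. In each of these, 1 of 100 splits or orders, the real one, gave as many. Splits of the samples at random leave the real differences in the residual spread, which lowers their counts, and breaks up the slides. Of 10 splits by whole slides, 0 called as many as the date, and the highest, 41992, places 42 of the 52 samples as the dates do, so it mostly repeats that contrast. The 4 splits that place 26 of the 52 as the dates do called 6639, 9999, 11124 and 14008 probes. Slides 3, 5 and 6, with 14008, place 50 of the 52 as date by transplanting does. Slides 2, 5 and 6, with 9999, and slides 3, 5 and 7, with 6639, place 40 of the 52 as transplanting does. Slides also hold blocks of hours of a series. These calls can therefore come from slides or from such contrasts, and the splits do not tell them apart. As many as transplanting were called by 4 splits, the highest 20760, with slides 2, 3 and 5 against the rest. The transplanting count was 4215 with slide as a random block and 0 with slide as a fixed term (limma, 10428 at an unadjusted p under 0.05), so chance among slides is not excluded for it. For the difference of daily curves between transplantings, a real count of 0 is reached by 100 of 100 splits by construction, which decides nothing (limma, 2639 at an unadjusted p under 0.05, and 19 called with a daily curve per date in the model), and the highest other split called 3339, which points to a structure of the samples.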

How the results depend on the processing

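Runs without slide 1 or slide 4, with scan day, on July or August alone for transplanting, with a daily curve per date, and with 1 probe per overlap group were chosen only after the result was seen. The test for a difference of daily curves between transplantings called 0 probes in 30 of 31 settings (limma, 1480 to 6194 at an unadjusted p under 0.05) and 19 with a daily curve per date in the model. Within 1.5 times their count stayed the rhythm over all series in 29 of 31 settings, the date in 29 of 33, transplanting in 24 of 33, the interaction in 25 of 28, the rhythm by date in 27 of 29, and the 24 h return in 9 of 15. The named probes kept their sign in all 591 runs and lost their call in 52. For 44kb3_11643 and 44kb3_960, with 30 runs each, the value is a range, whose sign cannot change. Many runs share nearly all samples and are not independent.

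Where a count moved further, the fixed slide term gave 1899 probes for date, 0 for transplanting (10428 at an unadjusted p under 0.05), 4411 for the interaction and 25728 for the rhythm by date. It leaves few samples that compare dates within a slide, and it could not be fitted to the 8 samples of the return. The random slide block gave 4215 for transplanting and 2840 for the interaction. With no array block, transplanting had 21508, the interaction 29371 and the return 5599. With no dye term the return had 0 (11609 at an unadjusted p under 0.05). Matched pairs as a block gave 27451 for transplanting, scan day 19505, July alone 22424, August alone 32972 and the runs without slide 1 3549. The date had 38862 in plants transplanted on May 22 alone. A size of at least 1 left 2362 for date and 180 for transplanting, and no limit on range 85497 for rhythm, both by construction. The bin from 14 to 16 h, the tallest, held 2820 probes with the 24 h period alone, under the 4156 from 16 to 18 h. Leaving out a series gave 1144 to 12359 for the return, with 1144 without the 84-day, 4050 without the 92-day and 8554 without the 64-day series.

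One probe per overlap group tests fewer probes, which lowers counts by construction: 21794 for rhythm over all series, 22871, 21428, 20383 and 19001 at 64, 56, 92 and 84 days, 37752 for date, 28131 for the rhythm by date and 7827 for the return. Elsewhere the cause was not tested. With the 75th percentile in place of Aquantile, 38.6% of date calls and 33.5% of transplanting calls were higher, against 51.4% and 45.7%. Higher calls of the return were 51.3% to 56.5% with other scalings and the deposited table, against 69.7%. The rhythm at 64 days without slide 1 and at 84 days without slide 4 was not fitted, since the 7 samples left were under the minimum set for a series. The mean over probes of a gene and all gene lists were not run. Signal over background limits the dim probes, which the filter leaves out.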

Other observations

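All counts here were chosen after the data had been seen and are descriptions with no test.

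Probes that differed strongly between dates were often rhythmic. Both sets were cut at a size of 1 on the log2 scale, so a shared size limit can by itself raise their overlap. Without the limit on range 85497 of the 96065 probes passed the rhythm test. Of the 2362 probes with a log2 difference of 1 or more between July and August, 1779 were rhythmic over all 4 series, or 75.3%, against 35.7% of all tested probes. Of all 58485 probes called between dates, 37.7% were rhythmic. Of the 13437 probes called for the 24 h return, 67.4% were rhythmic.

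Families of probes, by the start of their ID, differed in how many were rhythmic and in how many changed with date, with date shares from 53.0% to 69.1%. Of 27514 tested probes whose ID starts with 44kb3, 38.9% were rhythmic and 61.9% were called between dates. Of 3510 starting with eAryKoshi, 19.7% were rhythmic and 60.2% called between dates. Of 230 starting with 44kb3Koshi, 37.4% were rhythmic and 69.1% called between dates. Of 370 starting with Cuffnpc, 21.1% were rhythmic and 53.0% called between dates. The files do not say what these families stand for.

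Plants transplanted on May 30 and May 22 differed most at 04:00 among single hours, where the mean of both dates was lower by 1 or more for 1033 probes and higher for 204. At 02:00 the counts were 512 lower and 645 higher. Each hour rests on 2 pairs, and slides change between the hours.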
